A study of Ovis aries with 12 samples.

How the data were processed

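RNA was extracted with TriReagent from the dorsal and the ventral hippocampus of 12 adult Ile-de-France ewes, 6 under control conditions and 6 under chronic stress, per the labels' protocols. Equal amounts of RNA from 2 ewes were pooled for each library, so that each group holds 3 libraries, and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA. Both regions were taken from the same ewes. A p-value therefore treats pools as independent that share animals across regions, and variation between single ewes is averaged within a pool.

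The deposited table gave whole gene counts for the 12 libraries, one column each. Columns were matched to samples by the names in the sample descriptions, in which the dorsal libraries carry the prefix DG and the ventral ones vHip. The series record gives DG as short for dorsal, and whether the dentate gyrus alone was dissected is not stated. Per the submitters' processing notes, bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.9 and featureCounts 2.0.0 were used. The genome build, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Positions of genes are therefore not printed, reads of a gene and its antisense partner cannot be told apart, and genes with close copies are uncertain, among them ribosomal protein genes, which have many processed pseudogenes, BHMT and the growth hormone gene GH. TopHat2 with featureCounts is a spliced alignment and gene counting route that fits polyadenylated RNA from a tissue. Genes are identified by NCBI GeneID, and 412 genes with placeholder names were given symbols from a RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0, used for names only.

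The table held 33609 genes, of which 9337 had no count in any library. Library totals ranged from 12254743 counts in dorsal stress 3 to 53775720 in dorsal control 1, so that 1 CPM is 12.3 counts in the shallowest library. The 10 most abundant genes took 3.73% to 4.95% of counts. No pair of columns within a group held the same library: the closest differed by a chi-square of 21.6 per degree of freedom.

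Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 17806, normalized with TMM and fitted with the robust quasi-likelihood model, with 1 mean for each of the 4 groups. The 7 comparisons were dorsal against ventral over both conditions, in control and in stress, stress against control in dorsal, in ventral and averaged, and the difference of the stress effects. The quasi-likelihood F test was used with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The SE is the absolute log2 fold change divided by the square root of F. Principal components and library scores used log2 CPM.

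The 41 gene lists, the comparisons, the tests, the naming rule and most alternatives were fixed before the data were examined. The lists cover hippocampal poles, subfields and cell types, neighbouring tissues, and pathways of stress, plasticity, transmission, immunity and metabolism. Lists share members in 23 pairs. Of the 564 list genes 512 were tested, and 40 lists had at least 5 tested members. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares the list with all other genes, with Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation and fry were run beside it. The directional p-value of fry tests whether the genes of a list move, on balance, one way, its mixed p-value whether they change in either direction, and neither compares the list with other genes. Camera with the preset correlation, camera with an estimated correlation and fry called 16, 8 and 17 lists between regions, 17, 7 and 13 in control ewes, and 16, 10 and 13 in stressed ewes. For stress in dorsal tissue the numbers were 8, 0 and 0, in ventral tissue 7, 0 and 0, averaged 9, 0 and 0, and for the difference of stress effects 4, 0 and 0.

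Genes were named by rule. Among called genes with a symbol, a mean log2 CPM of at least 1 and every library of one group above every library of the other within condition, the 10 highest and 10 lowest log2 fold changes were taken. Where fewer than 5 genes were called, the 5 with the smallest p are given as values, with no limit on their mean log2 CPM. Up to 4 members of each list by smallest p were added, along with NR3C1, NR3C2, FKBP5, BDNF, CRH, CRHR1 and DCX for stress and WFS1, DCN, PROX1, CALB2 and TTR for region. Exceptions are the pituitary genes PRL, GH and CGA and the genes of the closing observations, which were chosen after their values were seen. Not every gene that the rule selects is named in the text, and the values of some are not reported here.

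Alternatives were RLE size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for replicate number, the mean of the choroid plexus or oligodendrocyte list as a covariate, only the 2 groups compared, and leaving out each library. The block was a term for number in edgeR for stress within a region. For region and the difference of stress effects it was an edgeR term for each condition and number. For averaged stress it was a limma-voom fit with a correlation (0.386) between libraries of one condition and number. The forms across regions take same-numbered dorsal and ventral libraries as pairs, which the labels do not state. Added after the data had been seen were the first residual factor as a covariate, counts thinned to the shallowest total, leaving out both control libraries numbered 1 or the 3 libraries farthest out on the first component, and a block within each region. The labels number the libraries of each group 1 to 3 and do not say what a number shares. Deviations from the group mean were correlated for same-numbered control and stress libraries at 0.712, 0.322 and 0.285 in dorsal and 0.241, 0.307 and 0.787 in ventral tissue, all above 0.1, so the numbers were taken to pair libraries for stress within a region. Not every library correlated best with its own number, since dorsal control 2 reached 0.568 with dorsal stress 3 and ventral control 1 reached 0.548 with ventral stress 2. Dorsal control 3 reached 0.243 with dorsal stress 2, so a swapped dorsal pairing would pass the same limit of 0.1. The limit therefore does not single out the numbers as pairs. Where the numbered pairing comes from is not given in the labels.

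The fit was tested on simulated data and on real counts with planted changes. In the simulated data 2-fold changes were found in 25.4% of planted genes for region, 10.4% for averaged stress and 0% for stress in dorsal or ventral tissue, and 4-fold changes in 77.3%, 68.2%, 15.2% and 28.8%. Planted in the real counts, 4-fold changes were found in 74.2% for region, 62.1% for averaged stress, 33.3% for dorsal stress, 31.8% for ventral stress and 3.03% for the difference of stress effects. In the simulated data, where genes were drawn independently of each other, a list with planted changes was called in all 7 comparisons and 0 of the 39 others. Real genes vary together, so this does not show how often lists are called by chance. In other splits of the real libraries the same test called a median of 5 lists between regions and 3 for averaged stress. Splits that move few libraries keep part of the true grouping, so these medians are not rates under chance alone. Reads were not analysed here, and no library was left out of the tests.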

Results

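Gene expression was measured by RNA sequencing in the dorsal and ventral hippocampus of adult Ile-de-France ewes, a French sheep breed, kept either under control conditions or under chronic stress. The hippocampus is a memory structure of the temporal lobe whose dorsal and ventral poles differ in their connections, and it is rich in receptors for stress hormones. Each library was a pool of RNA from 2 ewes, and 3 libraries were made for each of the 4 groups, 12 in all. Total gene counts were 53775720, 43101359 and 24952808 in dorsal control libraries 1 to 3 and 21244822, 19159056 and 12254743 in dorsal stress libraries 1 to 3. They were 45404523, 19801665 and 34648094 in ventral control libraries 1 to 3 and 24951732, 24910994 and 33132246 in ventral stress libraries 1 to 3. Every dorsal control library was deeper than every dorsal stress library. The table listed 33609 genes, and 17806 of them had counts high enough to be tested.

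The libraries of one group differed from each other along a common gradient. The first principal component of log2 CPM, the counts scaled to a common library total, held 50.04% of the variance and did not part the groups. The 3 ventral control libraries lay at -103, -21.0 and 105, and the dorsal control libraries at -81.3, 27.5 and 4.06. The second component held 18.9% and parted the regions, with dorsal libraries between -44.9 and -30.1 and ventral libraries between 18.7 and 57.8. Differences within the groups made up 73.0% of all variance. Each comparison below was run with a single fit of all 12 libraries in edgeR, and p-values were adjusted by the Benjamini-Hochberg method. Errors of log2 fold changes are standard errors (SE), and group levels are CPM with SD over 3 libraries.

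**Figure D1:**
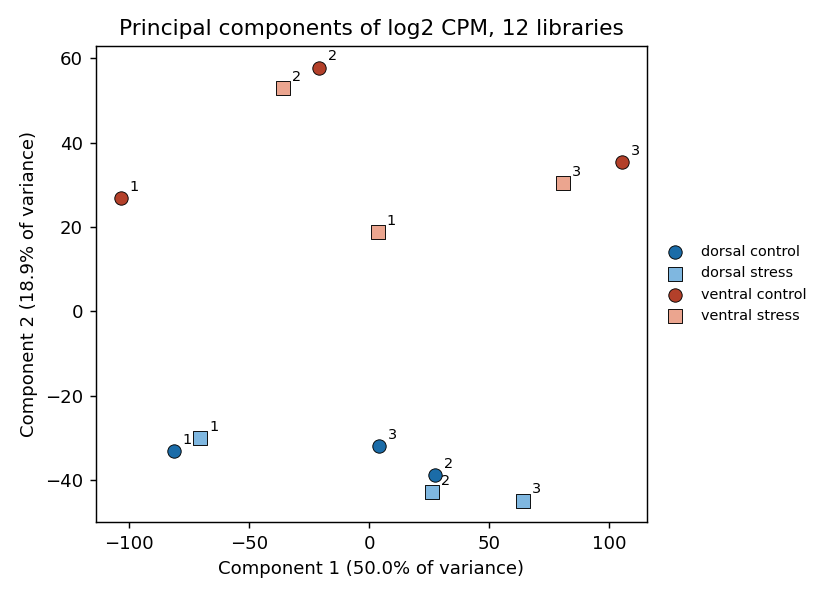
Scores of the 12 libraries on the first (x axis, 50.04% of variance) and second (y axis, 18.9%) principal components of log2 CPM; circles are control, squares are stress, blue is dorsal, red is ventral, and the number is the replicate. Dorsal libraries lie between -44.9 and -30.1 on the second component and ventral libraries between 18.7 and 57.8, while libraries of each group are spread along the first.

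The first comparison asked which genes differ between the dorsal and ventral hippocampus, taking the mean of both conditions. The neuropeptide gene ADCYAP1, which encodes PACAP, had the lowest log2 fold change of the genes named by the rule, -4.77 ± 0.28 (edgeR adjusted p = 8.07e-05), a 27.3-fold lower level in dorsal tissue. Its level was 1.63 ± 0.489 and 1.27 ± 0.384 CPM in dorsal control and dorsal stress against 37.8 ± 10.9 and 40.2 ± 12.8 CPM in ventral control and ventral stress (n = 3 each). VIPR1, a receptor for PACAP and vasoactive intestinal peptide, was also lower in dorsal tissue (-3.73 ± 0.29, adjusted p = 0.000226). Among genes higher in dorsal tissue were TTR, the thyroid hormone carrier transthyretin (3.54 ± 0.68, adjusted p = 0.0151), and DBH, the enzyme that makes noradrenaline from dopamine (3.21 ± 0.55, adjusted p = 0.00864). In total 803 genes differed between the regions in edgeR, 257 higher in dorsal and 546 higher in ventral hippocampus, with 2448 at an unadjusted p under 0.05. DESeq2 called 1474.

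Further genes with higher levels in dorsal tissue were C1QTNF5 (log2 fold change 3.44), AQP1 (3.24), the homeobox gene ONECUT2 (3.15), FREM3, an extracellular matrix protein (3.06), ZNF488 (2.78), HSPA2 of the Hsp70 chaperone family (2.49), ALDH8A1 (2.48) and the interleukin receptor subunit IL12RB1 (2.29). HSPA2 stood at 138 ± 8.40 and 169 ± 14.3 CPM in the dorsal groups against 24.6 ± 14.3 and 30.0 ± 16.4 CPM in the ventral groups (n = 3 each). On the ventral side were the surface protease FAP (-4.45), the neurexin ligand NXPH3 (-4.21), the complexin CPLX3, which acts in transmitter release (-4.03), BHMT (-3.97), TMIE (-3.81), the potassium channel subunit KCNG1 (-3.76), MYH15 (-3.68) and C24H16orf89 (-3.55). CPLX3 stood at 1.82 ± 0.165 and 1.87 ± 0.815 CPM in the dorsal groups against 32.7 ± 6.98 and 28.4 ± 15.8 CPM in the ventral groups (n = 3 each). For these 20 genes the SE lay between 0.28 and 0.88 and the edgeR adjusted p between 8.07e-05 and 0.0289. Within each condition every dorsal library lay on one side of every ventral library, which the naming rule required. Of 102 called genes refitted without each library in turn, 72 kept their call throughout. AQP1 lost its call without dorsal control 2, dorsal stress 2 or 3, ventral control 2, or ventral stress 2 or 3 (highest adjusted p = 0.0560). BHMT lost it without dorsal control 1 or 2, dorsal stress 2 or 3, ventral control 2, or ventral stress 2 or 3 (highest 0.0845), and C24H16orf89 without dorsal control 1, dorsal stress 2 or 3, or ventral control 2 (highest 0.0613).

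**Figure D2:**
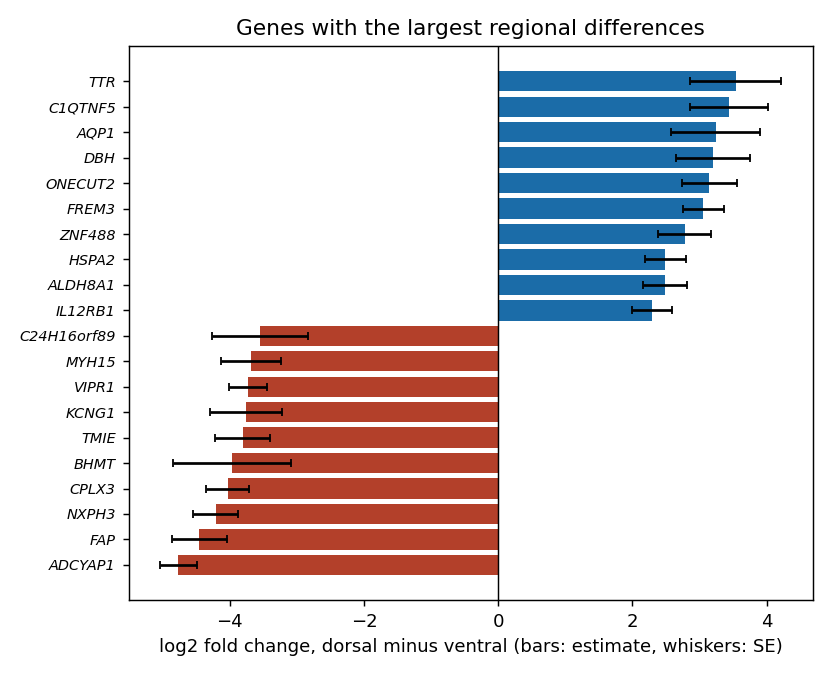
Log2 fold change of dorsal over ventral hippocampus (x axis) for the 20 genes with the highest and lowest values under the naming rule; bars are edgeR estimates over 12 libraries and whiskers are SE. Values run from -4.77 for ADCYAP1 to 3.54 for TTR.

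Markers of the rodent ventral pole were lower in dorsal than in ventral hippocampus of the ewe. Of 11 measured members 5 fell over all genes tested and 9 when adjusted over the list alone, 0 rose, and the median log2 fold change was -1.86 (camera adjusted p = 1.05e-17). They included the nuclear receptor NR2F2 (-2.38 ± 0.19), the proteoglycan DCN (-2.01 ± 0.28), NNAT (-1.98 ± 0.29) and TOX3 (-1.86 ± 0.34). The rodent dorsal pole list gave no such difference: 1 of its 5 measured members rose, SPATA13 (0.85 ± 0.13), and the camera adjusted p was 0.507. Its best known member WFS1 had a log2 fold change of -0.80 ± 0.32 (adjusted p = 0.284). The subiculum list also fell (camera adjusted p = 1.46e-08). Of its 8 members 4 fell and 1 rose over all genes, and 5 fell and 1 rose when adjusted over the list alone. The 4 that fell were NTNG1 (-3.52 ± 0.32), SLC17A6 (-3.08 ± 0.52), TSHZ2 (-2.23 ± 0.30) and the peptide gene NTS (-1.92 ± 0.27). With the choroid plexus score as a covariate SPATA13 lost its call (0.72 ± 0.18, adjusted p = 0.0503).

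Genes of the stress axis were found on both sides. Of 17 measured receptors and peptides 4 were lower and 1 was higher in dorsal tissue, and the same numbers held when adjusted over the list alone (camera adjusted p = 0.000123). Corticotropin-releasing hormone, CRH, had a log2 fold change of -3.08 ± 0.34 (adjusted p = 0.00102). It stood at 0.701 ± 0.0481 and 1.04 ± 0.214 CPM in the dorsal groups against 6.77 ± 3.05 and 7.90 ± 4.41 CPM in the ventral groups (n = 3 each). Its receptor CRHR2 was lower too (-1.80 ± 0.36, adjusted p = 0.0166), a call lost without dorsal stress 2 (adjusted p = 0.0595) and with counts thinned to one depth (adjusted p = 0.101). The mineralocorticoid receptor NR3C2, which binds cortisol with high affinity, was higher in dorsal tissue (0.91 ± 0.17, adjusted p = 0.0131), at 76.0 ± 5.65 and 98.9 ± 21.5 CPM against 41.4 ± 9.84 and 51.6 ± 10.5 CPM (n = 3 each). In the neurotrophin and growth factor list 1 of 13 members rose, BDNF (1.16 ± 0.24, adjusted p = 0.0220), and 1 fell (camera adjusted p = 0.538). The NR3C2 and BDNF calls ended with the choroid plexus score as a covariate (0.64 ± 0.23, adjusted p = 0.102, and 0.84 ± 0.34, adjusted p = 0.120). BDNF also lost its call without dorsal control 2 or 3, dorsal stress 2 or 3, ventral control 2 or ventral stress 3 (highest adjusted p = 0.0666).

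Some lists of transmitter systems, of neurons and of the striatum, a neighbouring tissue, were called as well. Of 8 striatal markers 3 fell, also when adjusted over the list alone (camera adjusted p = 5.47e-06), among them the enkephalin gene PENK (-3.42 ± 0.26) and the dopamine receptor DRD1 (-3.53 ± 0.32). DRD1 is counted again in the serotonin and monoamine receptor list, where 4 of 19 fell, 7 when adjusted over the list alone, with HTR1B, a serotonin receptor, at -3.37 ± 0.59 (camera adjusted p = 6.15e-05, adjusted p = 0.102 with an estimated correlation). Of those 4, ADRA2A (-0.87 ± 0.21) lost its call with no filter (0.0584), limma-voom (0.0655), the replicate block (0.103), the choroid plexus score (-0.73 ± 0.32, 0.134) and without 10 of the 12 libraries in turn. ADRB1 (-0.83 ± 0.18) lost it with the choroid plexus score (-0.93 ± 0.26, 0.0695) and without 8 of the 12. Of 13 GABA-A receptor subunits 2 fell, GABRA3 (-1.79 ± 0.32) and GABRE (-1.51 ± 0.23), and 5 when adjusted over the list alone (camera adjusted p = 0.000415, adjusted p = 0.339 with an estimated correlation). Among 22 glutamate receptors 3 fell and 0 rose, including the metabotropic GRM8 (-1.92 ± 0.29) and GRM4 (-1.80 ± 0.32), while adjusted over the list alone 5 fell and 3 rose (camera adjusted p = 0.216). The remaining gene, GRIN2C (-1.48 ± 0.36), lost its call with no filter (0.0646), limma-voom (0.0605), the replicate block (0.0938), thinned counts (0.0507), the choroid plexus score (-0.86 ± 0.50, 0.223) and without 11 of the 12 libraries in turn. Of 17 markers of inhibitory neurons 5 fell and 1 rose, 7 and 1 when adjusted over the list alone (camera adjusted p = 2.50e-05). NDNF (-1.18 ± 0.19) and LHX6, a transcription factor of interneurons (-0.93 ± 0.13), were lower and LAMP5 (0.86 ± 0.13) was higher. Of 9 markers of excitatory neurons 3 rose, with BHLHE22 at 1.60 ± 0.21, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00635, adjusted p = 0.0538 with an estimated correlation). Immediate early genes, which are switched on by neuronal activity, were lower in dorsal tissue in 4 of 21 cases, 6 when adjusted over the list alone, with NPAS4 at -2.48 ± 0.40 (camera adjusted p = 8.05e-05, adjusted p = 0.0869 with an estimated correlation). Of those 4, FOSB (-0.70 ± 0.17) and NR4A1 (-1.16 ± 0.28) lost their calls with limma-voom (-0.69 and -1.08, adjusted p = 0.0532 and 0.0642) and the replicate block (-0.69 and -1.10, adjusted p = 0.0736 and 0.0748). They also lost them with thinned counts (-0.63 and -1.13), with the choroid plexus score (-0.75 ± 0.25 and -0.70 ± 0.39, adjusted p = 0.0963 and 0.208), where NR4A1 shrank, and without 11 and 10 of the 12 libraries in turn (highest adjusted p = 0.126).

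Some lists of non-neuronal markers, of metabolism and of the thalamus, a neighbouring tissue, were called too. Whether dorsal and ventral dissections held unequal amounts of striatum, thalamus or meninges was not tested. Meningeal fibroblast markers fell in 4 of 10 cases, 9 when adjusted over the list alone (median -1.23, camera adjusted p = 4.51e-12), among them FMOD (-2.04 ± 0.30), COL1A2 (-1.24 ± 0.20) and the GABA transporter SLC6A13 (-1.22 ± 0.23). The extracellular matrix list, which shares 3 collagen genes with the meningeal list, fell in 5 of 22 members and rose in 1, and in 11 and 1 when adjusted over the list alone (camera adjusted p = 5.47e-06). All 16 oligodendrocyte markers had positive fold changes with a median of 0.69. Over all genes 1 passed, MOBP of the myelin sheath (0.92 ± 0.19), and 7 when adjusted over the list alone (camera adjusted p = 1.52e-08, adjusted p = 0.111 with an estimated correlation). MOBP lost its call without dorsal control 2 or 3, dorsal stress 2 or 3, ventral control 2, or ventral stress 1 or 2 (highest adjusted p = 0.0704). Ependymal markers rose as a group with 0 of 12 members passing, 2 when adjusted over the list alone (camera adjusted p = 0.00115, adjusted p = 0.165 with an estimated correlation). Of 10 genes of thyroid hormone signalling 2 rose, TTR among them, and 3 when adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.0538 with an estimated correlation). Thalamic markers fell in 2 of 7 cases, PRKCD (-1.47 ± 0.22) and SLC17A6, also when adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.283 with an estimated correlation). This list lost its call without ventral control 3 (adjusted p = 0.0673). Of 17 genes of cholesterol synthesis 4 fell, and 6 when adjusted over the list alone (camera adjusted p = 0.000132). Of those 4, 3 lost their calls with no filter (adjusted p from 0.0566 to 0.0816), with the replicate block (0.0568 to 0.0757) and with the choroid plexus score as a covariate (0.0889 to 0.0967), where log2 fold changes stayed between -0.52 and -0.43.

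The choroid plexus list was split. Of 13 members 3 rose and 1 fell, 4 and 3 when adjusted over the list alone, and its median was -0.14 against a mean of 0.50 (camera adjusted p = 0.122). TTR stood at 1560 ± 1120 and 573 ± 322 CPM in the dorsal groups and at 164 ± 216 and 40.2 ± 11.2 CPM in the ventral groups (n = 3 each), and the chloride channel gene CLIC6 rose by 1.87 ± 0.32. With the mean of this list as a covariate 773 genes were called, and TTR (4.29 ± 1.13, adjusted p = 0.0594), CLIC6 (1.86 ± 0.48, adjusted p = 0.0580) and AQP1 (2.04 ± 0.73, adjusted p = 0.103) lost their calls. So did BHMT (-4.85 ± 1.21), C24H16orf89 (-3.59 ± 1.07), MOBP (0.86 ± 0.30), GRM4 (-1.10 ± 0.39), COL1A2 (-1.11 ± 0.29), SLC6A13 (-1.08 ± 0.33) and PCP4 (-1.39 ± 0.39), with a highest adjusted p of 0.103. Over 102 refitted genes this covariate left a median of 101.6% of the log2 fold change and raised the median SE from 0.28 to 0.35. AQP1 and GRM4 also shrank. Calls ended too for the striatum (0.0704), excitatory neuron (0.272) and thyroid lists (0.430) with it. Markers of the hippocampal subfields did not pass as lists. CA2 markers included RGS14, higher in dorsal tissue (2.19 ± 0.32), and PCP4, lower (-1.70 ± 0.28), for a camera adjusted p of 0.676. Of 7 CA1 markers 1 fell, MPPED1 (-1.45 ± 0.14), with 0.0860, and the CA3, dentate granule cell and mossy cell lists had 0.919, 0.618 and 0.507. Dentate markers that fell included DSP (-1.92 ± 0.38), PDZD2 (-1.19 ± 0.29) and IGFBP5 (-0.52 ± 0.13), and the CA3 marker KCNQ5 fell too (-0.74 ± 0.17). PDZD2 and IGFBP5 lost their calls with limma-voom (adjusted p = 0.0631 and 0.0576) and KCNQ5 with the replicate block (0.0873). EOMES, a marker of neuronal progenitors, was the only 1 of 18 adult neurogenesis genes that passed (3.25 ± 0.66, camera adjusted p = 0.984 for the list). EOMES lost its call without dorsal control 2 or 3, ventral control 2 or ventral stress 3 (highest adjusted p = 0.0653). PROX1 and CALB2 did not pass (1.32 ± 0.75, adjusted p = 0.564, and -1.23 ± 0.34, adjusted p = 0.0742), though DESeq2 called CALB2 (adjusted p = 0.00871) and the fit with the first residual factor, the main axis of spread within groups, called WFS1, PROX1 and CALB2. The oestrogen receptor ESR1 fell (-1.21 ± 0.23), 1 of 5 sex steroid and prolactin receptors (camera adjusted p = 0.412), as did the clock gene NPAS2 (-0.92 ± 0.15), while 1 other of 18 clock genes rose (0.926).

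The remaining lists passed no camera test between regions. Adjusted p-values were 0.0536 for neocortex, 0.108 for glucocorticoid-induced genes, 0.190 for mural cells, 0.216 for the interferon response and 0.313 for ribosomal proteins. They were 0.444 for astrocytes, 0.542 for endothelial cells, 0.565 for oligodendrocyte precursors and for inflammation, 0.677 for microglia, 0.767 for the mitochondrial respiratory chain and 0.855 for the heat shock list. The erythrocyte list had too few measured members for a test, with HBB at -0.17 and AHSP at -0.45. Median, mean and camera direction differed in sign for the dorsal pole, neocortex, oligodendrocyte precursor, choroid plexus, heat shock, clock and adult neurogenesis lists. Of the 16 lists called by camera 8 held with an estimated correlation, those of the ventral pole, meninges, subiculum, extracellular matrix, striatum, inhibitory neurons, stress axis and cholesterol synthesis. With the mean of the oligodendrocyte list as a covariate 0 genes were called in edgeR (1318 at an unadjusted p under 0.05, smallest adjusted p = 0.0590). Of 102 called genes refitted with it, all 102 kept their sign with a median of 87.0% of the log2 fold change left, while the median SE rose from 0.28 to 0.44. The regions held 63.3% of the variance of that score. ADCYAP1 had -4.63 ± 0.50, NXPH3 -4.02 ± 0.61, C1QTNF5 3.95 ± 0.73 and NR2F2 -2.47 ± 0.34 with the covariate, whereas MOBP shrank to 0.18 ± 0.17 and BDNF to 0.50 ± 0.31. That covariate also ended the calls of the excitatory neuron (adjusted p = 0.0994), ependymal (0.304), thalamus (0.0699), thyroid (0.177) and oligodendrocyte lists (0.966). Of the 102 genes, which include list members counted above without a name, 31 lost their calls with the choroid plexus score, 11 with the replicate block, 9 with no filter, 6 with limma-voom, 6 with thinned counts and 11 without both control libraries numbered 1. With the first residual factor 3761 were called, and without the 3 libraries farthest out on the first component 500. That refit of fewer libraries ended 26 of the 102 calls (highest adjusted p = 0.219). Among them were BDNF (1.45 ± 0.32), EOMES (3.37 ± 1.00), CLIC6 (1.75 ± 0.47), ESR1 (-1.16 ± 0.26), LAMP5 (0.80 ± 0.18), BHMT (-3.87 ± 0.90) and C24H16orf89 (-3.86 ± 0.83), each with a larger SE (highest adjusted p of these = 0.141). FOSB, NR4A1, ADRB1 and GRIN2C lost their calls too. PDZD2, NEUROD2, ACAN and KCNQ5 did so with a smaller SE, and KCNQ5 shrank from -0.74 to -0.48. The number of region genes called also moved by more than 1.5 times without 1 library, to 452 without dorsal control 2 and 493 without dorsal control 3. It was 420 without dorsal stress 2, 505 without dorsal stress 3, 457 without ventral control 2, 465 without ventral stress 2 and 512 without ventral stress 3.

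**Figure D3:**
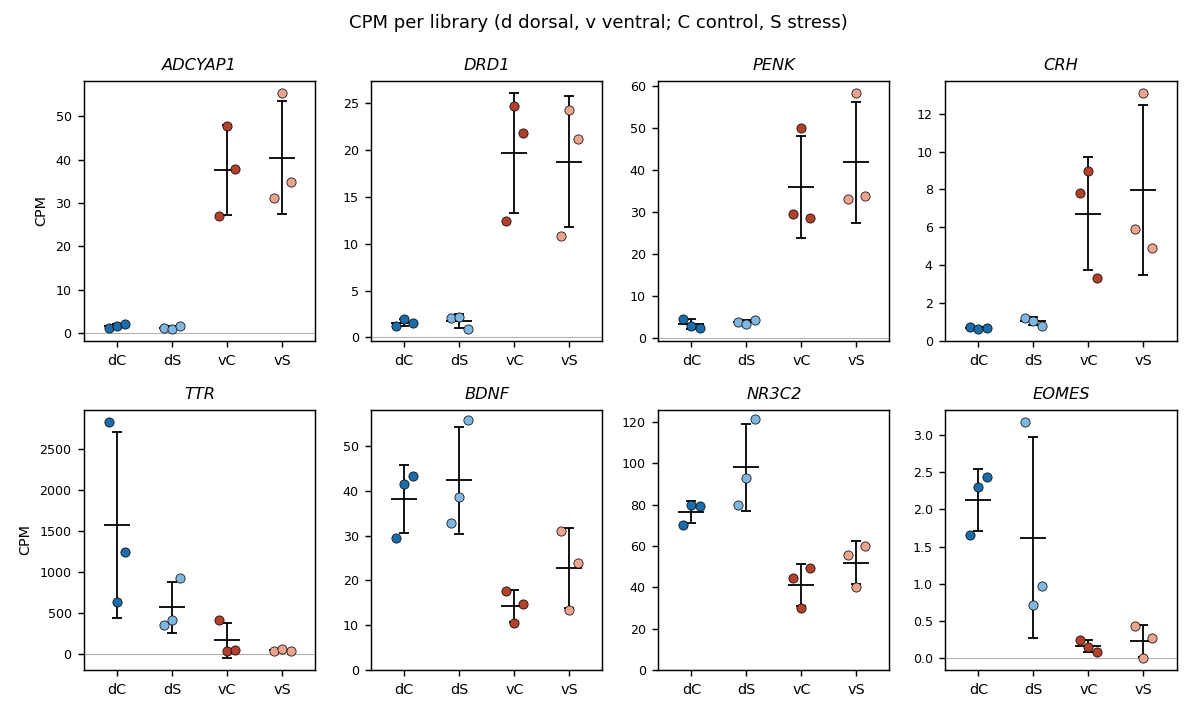
CPM (y axis, linear scale) of ADCYAP1, DRD1, PENK, CRH, TTR, BDNF, NR3C2 and EOMES in each library of dorsal control (dC), dorsal stress (dS), ventral control (vC) and ventral stress (vS); points are libraries, black lines are group means and whiskers are SD (n = 3). ADCYAP1 has means of 1.63 and 1.27 CPM in the dorsal groups and 37.8 and 40.2 CPM in the ventral groups.

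The regional difference was also taken within each condition. In control ewes 178 genes differed, 44 higher in dorsal and 134 higher in ventral hippocampus, and in stressed ewes 79 differed, 15 higher in dorsal and 64 higher in ventral. The calls overlapped, and 14 genes were higher in dorsal tissue in both conditions where independent draws would give 0.0371, and 60 were higher in ventral tissue in both where 0.482 would be drawn. Both sets of calls used the same estimate of the spread for each gene, which can favour the same genes in both. Independent draws are therefore not a strict reference, and the excess does not measure replication. Across all tested genes, which are not independent replicates, the regional fold changes in control and stressed ewes had a Pearson correlation of 0.746. The ventral pole list fell in control ewes (camera adjusted p = 8.30e-14) and in stressed ewes (6.31e-19), as did the subiculum (3.24e-09 and 1.39e-06), meningeal (2.04e-07 and 8.35e-16), striatum (2.20e-06 and 8.47e-05) and stress axis lists (0.000362 and 0.000156). Inhibitory neuron (0.000362 and 8.55e-06) and cholesterol synthesis genes (0.000111 and 0.00104) fell likewise, and these 7 lists held in both conditions with an estimated correlation. The extracellular matrix list fell too (0.00100 in control, adjusted p = 0.118 with an estimated correlation, and 3.23e-08 in stress).

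Most other list calls within a condition rested on the preset correlation. The oligodendrocyte list rose in control (camera adjusted p = 1.18e-05, adjusted p = 0.194 with an estimated correlation) and in stress (1.96e-10, adjusted p = 0.0765 with an estimated correlation). So did the ependymal list in control (0.0201, adjusted p = 0.312 with an estimated correlation) and in stress (0.000164, adjusted p = 0.111 with an estimated correlation). Excitatory markers rose in control (0.0286, adjusted p = 0.118 with an estimated correlation) and in stress (0.00233), where the call held. Immediate early genes fell in control (0.000677, adjusted p = 0.133 with an estimated correlation) and stress (5.59e-05, adjusted p = 0.0765 with an estimated correlation). Monoamine receptors fell in control (7.35e-05, adjusted p = 0.118 with an estimated correlation) and stress (0.000326, adjusted p = 0.127 with an estimated correlation). GABA-A receptors fell in control (0.00100, adjusted p = 0.370 with an estimated correlation) and stress (0.000813, adjusted p = 0.347 with an estimated correlation). Thalamic markers fell in control (0.0201, adjusted p = 0.293 with an estimated correlation) and stress (0.0375, adjusted p = 0.346 with an estimated correlation). The choroid plexus list (0.0240, adjusted p = 0.165 with an estimated correlation) and the neocortex list (0.0286, adjusted p = 0.118 with an estimated correlation) rose in control ewes, and thyroid hormone signalling rose in stressed ewes (0.000821), where it held. Of the lists called in any comparison, the neocortex list in control ewes was the only one whose median, mean and test differed in sign (median 0.28, mean -0.06, camera direction up).

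Both counts within a condition depended on single libraries. In control ewes 27 genes were called without dorsal control 1, 13 without dorsal control 2, 2 without dorsal control 3, 319 without ventral control 1, 24 without ventral control 2 and 113 without ventral control 3. The count was 77 without dorsal stress 2, 110 without dorsal stress 3 and 106 without ventral stress 3. In stressed ewes 13 were called without dorsal stress 1, 1 without dorsal stress 2, 2 without dorsal stress 3, 42 without ventral stress 1, 13 without ventral stress 2 and 18 without ventral stress 3. The same count was 46, 50 and 45 without dorsal control 1, 2 and 3, and 159 and 50 without ventral control 1 and 2. DESeq2 called 652 genes in control and 518 in stressed ewes, limma-voom 194 and 29, and edgeR with only the 6 libraries compared 0 and 0 (smallest adjusted p = 0.0506 and 0.0558). With the oligodendrocyte score as a covariate both counts were 0, with the choroid plexus score 68 and 182, and with the first residual factor 2003 and 1589. Without 1 library the excitatory, choroid plexus, ependymal, thalamus, neocortex and GABA-A lists lost their calls in control ewes, most often without ventral control 3 (thalamus adjusted p = 0.169, GABA-A 0.339, ependymal 0.147, neocortex 0.0911, choroid plexus 0.0679) or ventral control 1 (excitatory 0.120, choroid plexus 0.231, neocortex 0.273). The other losses in control came without ventral control 2 (excitatory and ependymal, 0.0990), dorsal control 1 (thalamus, 0.101), dorsal control 2 (neocortex, 0.0595) and dorsal control 3 (choroid plexus, 0.0581). With the choroid plexus score the excitatory (0.707), neocortex (0.405), oligodendrocyte (0.268) and striatum lists (0.152) lost their calls in control, and with the oligodendrocyte score the ependymal (0.562), excitatory (0.190) and choroid plexus lists (0.0656). Without both control libraries numbered 1 the neocortex (0.167), choroid plexus (0.0911) and excitatory lists (0.0523) did so, and without the 3 farthest libraries these 3 (0.285, 0.475 and 0.0600) and GABA-A (0.0835). In stressed ewes the oligodendrocyte score ended the calls of the oligodendrocyte (0.861), ependymal (0.173), thyroid (0.1215), thalamus (0.101), excitatory (0.0960) and cholesterol lists (0.0747). There the thalamus list lost its call without dorsal stress 1 (0.168) and ventral stress 3 (0.198), and the GABA-A list without ventral stress 3 (0.0907).

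The next comparison asked what chronic stress changed in the dorsal hippocampus. No single gene passed, and the 7 measured CA1 pyramidal cell markers rose as a group, all with positive log2 fold changes and a median of 0.55 (camera adjusted p = 0.000130, adjusted p = 0.0576 with an estimated correlation). MPPED1 had a value of 0.55 in that list. Choroid plexus markers fell as a group, with 4 of 13 positive and a median of -0.49 (camera adjusted p = 0.000379, adjusted p = 0.0971 with an estimated correlation), and CLIC6 had a value of -1.17. The named gene with the smallest p was POMC, which encodes the precursor of the pituitary hormone ACTH, with a log2 fold change of -5.54 ± 1.01 (edgeR adjusted p = 0.9999). It stood at 97.3, 26.8 and 17.5 CPM in dorsal control 1 to 3 and at 1.81, 0.458 and 0.645 CPM in dorsal stress 1 to 3. Other pituitary hormone transcripts were also lower on average in dorsal stress. PRL was at 56.8 ± 36.7 against 4.40 ± 3.81 CPM, GH at 19.5 ± 7.90 against 0.929 ± 0.779 CPM and CGA at 6.37 ± 4.46 against 0.504 ± 0.450 CPM (n = 3 each). Within dorsal control 1 to 3 PRL rose from 18.9 to 59.4 and 92.2 CPM where POMC fell.

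**Figure D4:**
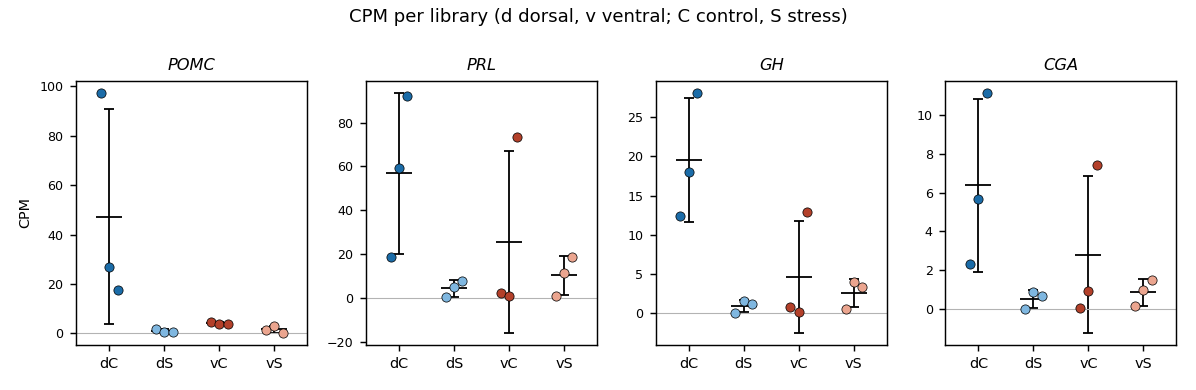
CPM (y axis, linear scale) of the pituitary hormone genes POMC, PRL, GH and CGA in each library of dorsal control (dC), dorsal stress (dS), ventral control (vC) and ventral stress (vS); points are libraries, black lines are group means and whiskers are SD (n = 3). POMC lies between 17.5 and 97.3 CPM in the dorsal control libraries and between 0.458 and 1.81 CPM in the dorsal stress libraries.

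A further 6 lists passed the preset camera test for stress in dorsal tissue, and 0 members of any list passed over all genes or adjusted over the list alone. Those with a positive median were the subiculum list with 8 of 8 members positive (0.24, camera adjusted p = 0.0208, adjusted p = 0.480 with an estimated correlation) and excitatory neurons with 9 of 9 (0.16, 0.0359, adjusted p = 0.234 with an estimated correlation). Oligodendrocyte precursors followed with 9 of 10 (0.28, 0.0350, adjusted p = 0.234 with an estimated correlation). Glutamate receptors had 20 of 22 positive (0.22, 0.0237, adjusted p = 0.480 with an estimated correlation) and monoamine receptors 12 of 19 (0.23, 0.00676, adjusted p = 0.480 with an estimated correlation). Ribosomal protein genes had 1 of 26 positive (-0.18, 0.00913, adjusted p = 0.706 with an estimated correlation). The CA1 call held without each library in turn and was lost with the choroid plexus score as a covariate (adjusted p = 0.0828). The other 7 lost their calls with that covariate or without both control libraries numbered 1. Without 1 library they lost their calls, 6 of them without dorsal control 1 (highest adjusted p = 0.937), 2 without dorsal control 2 (0.106) and 2 without dorsal control 3 (0.0711). The numbers were 4 without dorsal stress 1 (0.128), 3 without dorsal stress 2 (0.173) and 5 without dorsal stress 3 (0.952).

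None of the genes fixed for the stress response passed in dorsal tissue. The log2 fold changes were 0.17 ± 0.42 for the glucocorticoid receptor NR3C1, 0.38 ± 0.24 for NR3C2 and -0.41 ± 0.43 for FKBP5, a glucocorticoid-induced chaperone. They were 0.58 ± 0.47 for CRH, 0.15 ± 0.44 for its receptor CRHR1, 0.17 ± 0.34 for BDNF and 0.62 ± 0.48 for DCX, a marker of young neurons. The 3 stress libraries were all on the side of the fold change against the control mean for NR3C2, FKBP5, CRH and DCX and 2 of 3 for the others, and against the same-numbered control library FKBP5 had 2 of 3 and the rest the same numbers. After POMC the named genes ranked next by p were the T cell surface gene CD6 (2.17 ± 0.55), VGLL2 (3.25 ± 0.86), SDR9C7 (-3.10 ± 0.89) and the semaphorin receptor PLXND1 (0.63 ± 0.19). VGLL2 was near the floor, at 0, 0.0225 and 0.0393 CPM in dorsal control 1 to 3 and 0.0978, 0.204 and 0.323 CPM in dorsal stress 1 to 3. SDR9C7 was also under 1 CPM in every dorsal library. The smallest adjusted p of the comparison was 0.9999 in edgeR. In edgeR 0 genes had an adjusted p under 0.05 and 152 had an unadjusted p under 0.05, where 890.3 would be drawn by chance under uniform p-values. With 0 genes called still, the unadjusted count was 3355 with the choroid plexus score as a covariate and 1857 with the first residual factor. DESeq2 called 1 gene, POMC (-5.55, adjusted p = 3.75e-07), and limma-voom 0. Every library of one condition was above every library of the other for 423 genes higher and 490 lower in stress, against a chance share of 10% of all genes.

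The same question was asked of the ventral hippocampus. No single gene passed there, and CA1 markers again rose as a group, with 6 of 7 positive and a median of 0.22 (camera adjusted p = 0.0247, adjusted p = 0.344 with an estimated correlation). Dentate granule cell markers rose with 12 of 14 positive (0.27, camera adjusted p = 0.0227, adjusted p = 0.686 with an estimated correlation), and neocortex markers with 6 of 7 (0.16, 0.0295, adjusted p = 0.344 with an estimated correlation). Glucocorticoid-induced genes fell as a group, with 5 of 18 positive (-0.18, 0.0295, adjusted p = 0.344 with an estimated correlation), and FKBP5 had a value of -0.56 with 3 of 3 stress libraries below the control mean and 2 of 3 below the same-numbered control library. Oligodendrocyte markers fell with 4 of 16 positive (-0.30, 0.0295, adjusted p = 0.686 with an estimated correlation). Ependymal markers fell with 1 of 12 (-0.24, 0.0295, adjusted p = 0.686 with an estimated correlation) and ribosomal protein genes with 2 of 26 (-0.23, 0.0295, adjusted p = 0.7999 with an estimated correlation). No list member passed over all genes or adjusted over the list alone.

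The named genes ranked highest by p in ventral tissue were PLG, plasminogen (3.03 ± 0.77), the activity-regulated gene ARC (1.52 ± 0.40), MYLK2 (1.96 ± 0.56), ALDH8A1 (1.56 ± 0.46) and FAM163B (1.28 ± 0.39). All 3 stress libraries were above the control mean for each of them, and the smallest adjusted p of the comparison was 0.9998 in edgeR. PLG was near the floor, at 0, 0.0486 and 0.0559 CPM in ventral control 1 to 3 and 0.2345, 0.3196 and 0.3278 CPM in ventral stress 1 to 3. MYLK2 was also under 1 CPM in every ventral library. The stress genes had log2 fold changes of 0.11 for NR3C1, 0.32 for NR3C2, 0.22 for CRH, -0.16 for CRHR1, 0.66 ± 0.34 for BDNF and -0.13 for DCX. In direction, 1 of 3 stress libraries was on the side of the fold change against the control mean for NR3C1 and CRH and 2 of 3 for the others, and against the same-numbered control library 3 of 3 for NR3C2 and BDNF and 2 of 3 for the others. In edgeR 0 genes had an adjusted p under 0.05 and 142 an unadjusted p under 0.05, a number that was 698 without ventral control 3 and 2134 with the first residual factor, and DESeq2 and limma-voom called 0 and 0. Every library of one condition was above every library of the other for 245 genes higher and 265 lower in stress, against a chance share of 10%. All 7 list calls were lost without 1 library, 6 without ventral control 1 (highest adjusted p = 0.862), 3 without ventral control 2 (0.419) and 5 without ventral control 3 (0.575). The numbers were 2 without ventral stress 1 (0.208), 3 without ventral stress 2 (0.563) and 7 without ventral stress 3 (0.740). With no filter on low counts all 7 had adjusted p-values between 0.0615 and 0.0821, and without the 3 libraries farthest out on the first component 1 gene was called.

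Averaged over both regions, CA1 markers rose in stress as a group, with 6 of 7 positive and a median of 0.49 (camera adjusted p = 0.000117, adjusted p = 0.0531 with an estimated correlation), and all 6 stress libraries were above the control mean of their region. Monoamine receptors rose with 15 of 19 positive (0.28, camera adjusted p = 0.0151, adjusted p = 0.374 with an estimated correlation), and dentate granule cell markers with 12 of 14 (0.21, 0.0151, adjusted p = 0.775 with an estimated correlation). Glutamate receptors rose with 19 of 22 (0.17, 0.0230, adjusted p = 0.424 with an estimated correlation) and neocortex markers with 6 of 7 (0.14, 0.0315, adjusted p = 0.264 with an estimated correlation). Lists that fell were ribosomal proteins with 1 of 26 positive (-0.20, 0.00321, adjusted p = 0.927 with an estimated correlation) and choroid plexus with 3 of 13 (-0.36, 0.0230, adjusted p = 0.264 with an estimated correlation). Glucocorticoid-induced genes had 4 of 18 positive (-0.12, 0.0230, adjusted p = 0.264 with an estimated correlation) and interferon response genes 5 of 20 (-0.12, 0.0315, adjusted p = 0.424 with an estimated correlation). Stress libraries lay 22.9 further along the first component than control libraries on average, 23.2 in dorsal and 22.6 in ventral tissue. Along that component dentate granule cell markers had a mean slope of 0.447 and 75 cytosolic ribosomal protein genes one of -0.468, in log2 CPM per SD of the component. The CA1 call held without each library in turn. The other 8 lists lost their calls with the choroid plexus score as a covariate or without both control libraries numbered 1. Without 1 library, 5 lost their call without dorsal control 1 (highest adjusted p = 0.285), 2 without dorsal control 2 (0.185) and 2 without dorsal control 3 (0.0864). A further refit ended 5 calls without dorsal stress 1 (0.249) and 4 without dorsal stress 3 (0.140). In ventral libraries the numbers were 6 without ventral control 1 (0.674), 5 without ventral control 2 (0.127), 4 without ventral control 3 (0.291), 3 without ventral stress 1 (0.109), 2 without ventral stress 2 (0.0906) and 5 without ventral stress 3 (0.327).

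The named genes ranked highest by p for averaged stress were POMC (-3.48 ± 0.65), PLG (2.46 ± 0.49), the lipid transporter ABCA6 (-0.65 ± 0.16), SDR9C7 (-2.34 ± 0.59) and GIMAP6 (-0.99 ± 0.25). All 6 stress libraries lay in that direction for each, and the smallest adjusted p was 0.9999 in edgeR. SDR9C7 was under 1 CPM in every library, and PLG in every control and every ventral library. DESeq2 called POMC (-3.48, adjusted p = 2.07e-05) and PLG (2.57, adjusted p = 0.0182). The astrocyte filament GFAP had a value of -0.38, TTR -1.74 and ARC 0.83. For the stress genes the values were 0.14 for NR3C1, 0.35 for NR3C2, -0.49 for FKBP5, 0.42 for BDNF, 0.40 for CRH, -0.00 for CRHR1 and 0.24 for DCX, of which FKBP5 had 6 of 6 libraries in its direction against the control mean of the region and NR3C2 5 of 6. Against the same-numbered control library FKBP5 had 4 of 6 and NR3C2 6 of 6. In edgeR 0 genes had an adjusted p under 0.05 and 308 an unadjusted p under 0.05, against 920 without ventral control 3, 2150 with the choroid plexus score and 3401 with the first residual factor. Other settings lowered the share of genes at an unadjusted p under 0.05, from 1.73% to 0.730% with the replicate block and 1.28% without dorsal stress 3. DESeq2 called 12 in all, limma-voom 0 and edgeR without the 3 libraries farthest out on the first component 1. With the first residual factor as a covariate 409 were called, 258 higher and 151 lower, a count that as many as 55 of 100 splits of the libraries matched. Across genes, which are not independent replicates, the stress effects in the 2 regions had a Pearson correlation of 0.401 and a Spearman correlation of 0.416, and of 24 genes at an unadjusted p under 0.05 in both, 23 had the same sign. Both regions came from the same ewes, so differences between animals alone can make the effects agree, and this agreement is not replication. The Pearson correlation was 0.198 without dorsal control 1, 0.270 without dorsal stress 3, 0.176 without ventral control 1, 0.271 without ventral control 2 and 0.164 without ventral stress 3.

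The last comparison tested whether the effect of stress differed between the regions. Meningeal fibroblast markers had a lower stress effect in dorsal than in ventral tissue, with 2 of 10 differences positive and a median of -0.39 (camera adjusted p = 0.00306, adjusted p = 0.402 with an estimated correlation). Extracellular matrix genes had 7 of 22 positive (-0.12, 0.0123, adjusted p = 0.402 with an estimated correlation). Choroid plexus markers had 6 of 13 positive (-0.20, 0.0167, adjusted p = 0.402 with an estimated correlation). Subiculum markers had a higher effect in dorsal tissue, with 6 of 8 positive (0.54, 0.0123, adjusted p = 0.402 with an estimated correlation). No list member passed over all genes or adjusted over the list alone. The named genes ranked highest by p were the kinase CAMK1G (0.73 ± 0.21), POMC (-4.13 ± 1.25), MYLK2 (-2.56 ± 0.78), VGLL2 (3.32 ± 1.02) and the steroid enzyme gene HSD17B3 (-2.67 ± 0.82), none of which passed in edgeR. MYLK2 and HSD17B3 were under 1 CPM in every library, and VGLL2 in every dorsal library. In edgeR 0 genes had an adjusted p under 0.05 and 46 an unadjusted p under 0.05. That number was 134 without ventral control 3, 109 without ventral stress 3, 102 without ventral control 1, 374 with the choroid plexus score and 297 with the first residual factor, and DESeq2 and limma-voom called 0 and 0. Each of the 4 list calls was lost without the 3 libraries farthest out on the first component (highest adjusted p = 0.843) and without at least 1 single library. All 4 were lost without dorsal stress 2 (highest adjusted p = 0.137) or ventral control 3 (0.553). The number was 3 without dorsal control 3 (0.170) or ventral control 1 (0.472), and 2 without dorsal control 1 (0.180), dorsal stress 1 (0.291) or ventral stress 2 (0.171). One list each was lost without dorsal control 2 (0.163), dorsal stress 3 (0.0998), ventral control 2 (0.0709), ventral stress 1 (0.191) and ventral stress 3 (0.252).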

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

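The tests of neighbouring tissue and of the gradient between libraries were chosen only after the results were seen, as was the count over splits that part numbered pairs. The other counts over splits were planned, apart from that of genes at an unadjusted p under 0.05. With the preset correlation the stress effect differed between dorsal and ventral hippocampus for 4 gene lists, meningeal fibroblast markers (camera adjusted p = 0.003064), subiculum markers (0.01226), extracellular matrix genes (0.01226) and choroid plexus markers (0.01666), and with an estimated correlation it differed for 0 (adjusted p = 0.402 for each). Chance cannot be excluded, since 51 of 100 splits called at least 4 lists and the highest other gave 11. Unequal amounts of neighbouring tissue between dissections may contribute: the members of the choroid plexus list moved together within groups more than 77.72% of random lists, and those of the meningeal list more than 94.43%, short of the 95% set for the test, while the choroid plexus score as a covariate left the meningeal list at 0.303 and the extracellular matrix list at 0.736. With the first residual factor as a covariate 2 of the 4 lists stayed under an adjusted p of 0.05, meningeal (0.0226) and extracellular matrix (0.0413), and the choroid plexus (0.0727) and subiculum lists (0.0664) did not, so the gradient between libraries stays open too. A regional difference in the response to stress is the biological explanation the design names, and it cannot be told apart from either by these values.

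Splits of the libraries were counted for each result. Between regions 3 of 100 splits called as many genes (803 against 8393 in the highest other), and 4 of 100 called as many lists (16 against 18). Both shares are under 0.05. For genes at an unadjusted p under 0.05, however, 13 of 100 splits gave as many (2448 against 9793). The splits therefore argue against chance for the adjusted calls but do not exclude it. Splits that part same-numbered dorsal and ventral libraries were not counted apart, although both regions came from the same ewes. The 2 other splits with the most genes parted libraries along the first component by at least 95.1, where the real split differs by 9.91, which points to a structure of the samples. For averaged stress 4 of 100 splits called as many lists (9 against 11), but of the 32 splits that part every numbered pair of control and stress libraries 2 did (6.25%), so chance cannot be excluded. With the replicate block, here a limma-voom fit, 3 of those 9 lists, choroid plexus, neocortex and interferon, had an adjusted p of 0.0530. For the genes 100 of 100 splits called as many (0 against 6071). For the difference of stress effects 100 of 100 splits called as many genes (0 against 6294). The 3 splits with the most genes in each of these comparisons again followed the first component. The correlation of stress effects between regions was matched in 11 of 100 splits (0.401 against 0.747), so chance cannot be excluded. Those splits relabelled dorsal and ventral libraries separately. They therefore do not show the agreement that shared ewes would give without an effect of stress.

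The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. Between regions in control ewes 1 of 10 splits gave as many genes (178 against 0 in the highest other) and 1 of 10 as many lists (17 against 13), and in stressed ewes 1 of 10 as many genes (79 against 1) and 1 of 10 as many lists (16 against 8). For stress in dorsal tissue 10 of 10 splits gave as many genes (0 against 0) and 2 of 10 as many lists (8 against 8), and in ventral tissue 10 of 10 (0 against 1) and 3 of 10 (7 against 11). Among the 4 splits that part all 3 numbered pairs, as the real one does, the highest other called 8 lists in dorsal and 1 in ventral tissue.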

How the results depend on the processing

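The choice of residual factor, thinning and the joint removal of libraries were tests chosen after the results were seen. Region genes called were 803 and became 1474 with DESeq2, 0 with the oligodendrocyte covariate, 3761 with the residual factor (which removes spread within groups by construction), 500 without the 3 libraries farthest out, and 420 to 1091 without 1 library. In control ewes 178 became 652 with DESeq2, 68 with the choroid plexus covariate, 0 with the oligodendrocyte covariate, 0 with only 2 groups (fewer libraries for the spread), 2003 with the residual factor, 58 without both control libraries numbered 1, 2 without the 3 farthest, and 2 to 319 without 1 library. In stressed ewes 79 became 518 with DESeq2, 29 with limma-voom, 182 and 0 with the choroid plexus and oligodendrocyte covariates, 0 with only 2 groups, 1589 with the residual factor, and 1 to 159 without 1 library. Stress counts of 0 became 1 in dorsal and 12 averaged with DESeq2, 409 averaged with the residual factor, and 1 in ventral and 1 averaged without the 3 farthest. They stayed at 0 without any 1 library, and the count for the difference of stress effects was 0 in every setting run. The correlation of stress effects ranged from 0.164 to 0.432 without 1 library. Directions of lists reversed as follows. The oligodendrocyte list did so in control ewes with its own covariate (adjusted p = 0.948) and for stress in ventral tissue without both control 1 libraries (0.853) or the 3 farthest (0.338), with a range of 4.87e-05 to 0.857 without 1 library, reversed without ventral control 1. The choroid plexus list reversed with its own covariate in control ewes (0.777) and for the difference of stress effects (0.873). Ribosomal proteins reversed for stress in dorsal tissue without both control 1 libraries (0.923) or the 3 farthest (0.943), with 2.52e-06 to 0.952 without 1 library, reversed without dorsal control 1 (0.937). In ventral tissue they reversed without both control 1 libraries (0.396), with 1.69e-06 to 0.712 without 1 library, reversed without ventral control 1 (0.360) and ventral stress 3 (0.712), and averaged without both control 1 libraries (0.554). The cause was not tested, except that a list's own covariate removes it by construction. The CA1 list kept its averaged call in 24 of 26 settings (adjusted p from 1.103e-05 to 0.0663). Those 24 settings all used camera with the preset correlation. The call was lost with camera at an estimated correlation and with fry, the only settings that did not use it. The count therefore does not show that the CA1 call holds without the preset correlation. With the replicate block region counts were 823, with 651 of the 803 genes shared, 156 in control ewes, with 109 of 178 shared, and 57 in stressed ewes, with 30 of 79 shared, so region calls were both gained and lost, and stress counts were 0 in dorsal, ventral and averaged tests and for the difference. Across regions the same-numbered libraries correlated at 0.717, -0.119 and 0.373 in control and 0.208, -0.234 and 0.761 in stress, and not every library correlated best with its own number. The block moved the neocortex list in control ewes to 0.0623 and, in its limma-voom form, the averaged choroid plexus, neocortex and interferon lists to 0.0530. It changed no other list call. At one common depth 735, 143 and 84 region genes were called, and stress counts stayed at 0.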

Other observations

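The genes below and all tests of the gradient and of pituitary RNA, thinning to one depth included, were chosen only after the results were seen. They are single genes, for which no list or enrichment was tested. The log2 fold changes of dorsal over ventral were -2.66 ± 0.43 for the histamine receptor HRH3, -2.53 ± 0.36 for the orexin receptor HCRTR1, -2.35 ± 0.27 for TACR1, the receptor of substance P, -2.06 ± 0.24 for the muscarinic receptor CHRM4 and -1.80 ± 0.28 for the cholecystokinin receptor CCKBR (edgeR adjusted p from 0.00102 to 0.00640). HRH3 stood at 10.1 ± 4.42 CPM in dorsal and 63.9 ± 32.8 CPM in ventral libraries (SD, n = 6 each). GLP1R, the receptor of glucagon-like peptide, went the other way (1.30 ± 0.20, adjusted p = 0.00533). The nitric oxide synthase NOS1 (-1.59 ± 0.21, adjusted p = 0.00236) and ASS1, which resupplies its substrate arginine (-3.26 ± 0.25, adjusted p = 0.000226), were both lower in dorsal tissue, and ASS1 stood at 6.398 ± 1.93 against 61.1 ± 16.7 CPM. So was the potassium channel gene KCNK12 (-3.15 ± 0.24, adjusted p = 0.000226).

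GAP43, a growth cone protein, was at 145 ± 27.5 CPM in dorsal and 624 ± 161 CPM in ventral libraries (SD, n = 6 each), a log2 fold change of -2.11 ± 0.21 (edgeR adjusted p = 0.000539). The ephrin EFNA5 (-2.36 ± 0.25), the Eph receptor EPHA8 (-1.95 ± 0.23), the repellent SLIT2 (-1.88 ± 0.26), the cadherin CDH13 (-1.75 ± 0.23) and the semaphorin receptor NRP2 (-0.97 ± 0.13) were lower in dorsal tissue too, while the semaphorin SEMA7A was higher (1.64 ± 0.20). The link protein HAPLN4 of perineuronal nets (-2.61 ± 0.31) and the calcium sensors NCALD (-1.38 ± 0.13) and VSNL1 (-0.98 ± 0.13) were lower, and the growth factor HBEGF (1.46 ± 0.14) and the synaptic pentraxin NPTX1 (1.19 ± 0.20) were higher. For every gene of these 2 paragraphs all 6 dorsal libraries lay on one side of the ventral mean of their condition, and the call held without each library in turn. With the choroid plexus score as a covariate HRH3 (-1.83 ± 0.51), CCKBR (-1.23 ± 0.34) and NPTX1 (0.98 ± 0.28) lost their calls (highest adjusted p = 0.0694), with smaller folds and larger SE. With the oligodendrocyte score 0 genes were called. The SE of all 21 genes grew, by a median factor of 1.59, and the fold change shrank for 17 and grew for 4, with a median of 86.8% left. The share ran from 59.7% for NPTX1 (0.71 ± 0.26) to 121% for SLIT2 (-2.28 ± 0.48), and HRH3 (-1.69 ± 0.56) and HCRTR1 (-1.58 ± 0.54) shrank nearly as much as NPTX1.

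The gradient between libraries of one group, 50.04% of variance, recurred in all 4 groups. After all libraries were thinned to one total the first component held 54.02%. Thinning evens out the sampling noise of unequal totals but leaves the expected CPM of a gene unchanged. This value therefore does not decide on depth, which stays open. Shares of cell types may contribute and stay open: 0 of 16 cell type lists had slopes on the component tighter than 95 of 100 random lists, but the mean slope of dentate granule markers, 0.447, lay above 99.98% of random lists (SD over genes 0.355). RNA or library quality acting on short against long transcripts stays open too, since all 12 gene families had mean slopes on the side of their size class, 9 of 12 beyond 95 of 100 random lists, 6 of 6 with short proteins and 3 of 6 with long ones. Of the 409 genes called for averaged stress with the residual factor as a covariate, 97.8% moved as a shift along the gradient would, against 74.0% of all genes. Factor and slopes come from the same libraries, and the factor shrinks the error of genes that follow the gradient. Such genes are favoured among the calls, so this share is no independent test of the gradient. Chance cannot be excluded for the count of 409, since 55 of 100 splits called as many (10240 in the highest other), while no biological explanation was tested.

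Transcripts of anterior pituitary hormones were present in libraries of the hippocampus and were highest on average in dorsal control. PRL, GH and CGA rose and fell together over the 12 libraries, with the lowest of their pairwise correlations at r = 0.885 between GH and CGA (rho = 0.909, permutation p = 2e-04 and 8e-05, adjusted p = 4e-04 for r over 6 pairs of genes, r = 0.796 without the 2 farthest libraries), in line with pituitary RNA carried into some libraries. POMC followed PRL less closely (r = 0.391, permutation p = 0.208, adjusted p = 0.208, rho = 0.448, permutation p = 0.148, r = 0.301 without the 2 farthest libraries), so the same source stays open for it. The POMC fold change was -5.45 ± 1.01 (SE) at one common depth. Thinning leaves the expected CPM of a gene unchanged, so this value could hardly move and does not decide on depth. Chronic stress stays open as well, because an exact two-sided permutation test of 3 libraries against 3 gave p = 0.1, the smallest it can give.

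A set of 9 genes was on in some libraries, at 25% or more of the highest CPM of the gene, and off in all others, at 5% or less. Each had a highest CPM of at least 5 and was on in at least 3 libraries and off in at least 3. Genes whose share of on libraries differed widely between the regions were left out. That choice can raise the matches across regions for same and different numbers alike. Same-numbered dorsal and ventral libraries matched in 8, 7 and 5 of the 9 genes in control and in 7, 5 and 9 in stress, and differently numbered ones of a condition in 2 to 7.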
